A study of Homo sapiens with 6 samples.

How the data were processed

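RNA was measured by sequencing in 6 libraries of human intrahepatic biliary epithelial cells, 3 given vehicle and 3 given recombinant human TGF-beta at 10 ng per ml for 48 hours. The groups and replicate numbers come from the labels. Per the labels' protocols the cells were grown in H69 medium, RNA was extracted with a Qiagen kit, and libraries followed standard Illumina protocols. Neither strand, read length nor read pairing is given in the sources used here. The submitters' processing notes name TopHat2 2.1.0, featureCounts and edgeR with the genome build GRCh38 (hg38), without saying which step each tool served. The annotation release is not given in the sources used here.

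The authors deposited a table of raw counts, whole numbers of reads per gene and library, with the coding length of each gene in bases (an annotation column of unit other) beside them. It holds 64253 genes, of which 60107 lie on reference chromosomes and 4146 on other sequences such as alternate haplotypes. A second table deposited by the authors gives RPKM per library, named per the file headers. The library size behind the authors' RPKM was 1.05 to 1.13 times the sum of each library's gene counts. That table also gives the authors' log2 fold change, log2 mean CPM, likelihood-ratio score, p-value and adjusted p-value, named per the file headers. It repeats 5579 gene identifiers, so only the 56391 genes listed once were matched to the counts. For 100% of these, the authors' deposited log2 fold change lay within 0.001 of an edgeR likelihood-ratio fit on the unfiltered counts. RPKM values were used only to read their scale and enter no test.

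In each library, more genes had a count of 2 than a count of 1, and more had a count of 4 than a count of 3. In vehicle replicate 1, for example, 2371 genes had a count of 2 and 1961 a count of 1. Even counts are in excess where the mates of a read pair are counted separately, and counting intervals are then too narrow. Gene symbols and positions are those of the count table. The authors' counting could split reads between close paralogs or pseudogenes, and without a stated strand setting it cannot separate a gene from an overlapping or antisense gene. Among tested genes, 477 pairs overlapped in position with counts within 15% of each other.

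Total counts per library were 38898263, 49062218 and 56867256 in vehicle replicates 1 to 3 and 55112685, 56568614 and 56188502 in TGF-beta replicates 1 to 3. A count of 3, the upper limit that a count of 0 allows, stands for 0.0528 to 0.0771 CPM. Exact 95% intervals and these floors cover counting error only. If mates were counted separately, the floors are too low as well. Within each group, pairs of libraries differed by more than sampling noise, with a mean chi-square per gene of 8.23 to 21.8. Sampling alone gives about 1, or somewhat more if mates were counted separately. All 6 were therefore kept as separate libraries. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

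The test, its samples, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. R 4.3.3 was used with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes passing edgeR's filterByExpr with default settings were kept (20639), TMM factors were computed, and edgeR's quasi-likelihood test compared the 2 groups without further terms. Genes were called at a Benjamini-Hochberg adjusted p of 0.05 or less, over all genes tested. CPM values use the TMM-scaled library sizes, and means are given with the SD over 3 libraries. Standard errors of log2 fold changes come from the spread of log2 CPM (prior count 2) within the groups.

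The 31 gene lists were tested with limma's camera, 2-sided, with a preset correlation of 0.01 on log2 CPM and Benjamini-Hochberg adjustment over the lists. Camera asks whether a list shifted against all other genes. An estimated correlation and fry, which asks whether the genes of a list move on balance one way, were the alternatives. With an estimated correlation, camera also takes its degrees of freedom from the few libraries and not from the number of genes. Its p-values can then rise even where the correlation does not. For each list the members called are counted over all genes tested, and again with p-values adjusted over the list alone. Some genes sit on more than one list.

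Genes were named by a fixed rule. The first part takes the 12 largest rises and the 12 largest falls among called genes with no overlap between groups and a mean of at least 10 CPM in the higher group, leaving out clone-style names and sex-linked marker genes. The second part takes from each list up to 3 called members with the largest absolute change, with the same minimum of 10 CPM. The last part names SMAD7, FN1, COL1A1, CTGF, ACTA2, CDH1, VIM, KRT7, KRT19 and EZH2 whatever their values. Some genes that the rule picks are not reported here. Any other gene named, mostly to spell out counts of 5 or fewer, was chosen after its values were seen.

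The gene fit was tested on simulated counts for the same 20639 genes, with 50 genes changed at each fold size. The edgeR test recovered 70% of genes changed 1.5-fold, 88% at 2-fold and 100% at 4-fold, and 8.70% of its calls were false. The changed genes were drawn from those above a minimum mean count. They were a much smaller share of all genes than the 39.5% called in the data, so recovery in the data may differ. Among 200 simulated unchanged lists, camera took 5 and fry 12 past an unadjusted p of 0.05. The simulated genes were drawn independently of each other, so these numbers do not test the preset correlation. Alternatives were relative log expression, upper-quartile and library-total scaling, no count filter, a filter of 1 CPM in at least 3 libraries, DESeq2, limma-voom, a replicate block, glmTreat against a fold of 1.2, a minimum of 2-fold, and leaving out each library in turn. Added after the data were seen were a likelihood-ratio test without filter, reference chromosomes only, 1 gene per overlapping pair, and some of the alternatives for single lists. Levels of sex-linked marker genes are not reported.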

Results

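Gene expression was measured by RNA sequencing in HiBEC, cells that the labels describe as human intrahepatic biliary epithelial cells, the epithelium that lines the bile ducts inside the liver, also called cholangiocytes. The 3 libraries of cells given vehicle were compared with 3 libraries of cells given TGF-beta, a secreted signalling protein that acts through SMAD transcription factors, at 10 ng per ml for 48 hours. The comparison asks which genes change in these cells under TGF-beta. Total counts per library ranged from 38898263 in vehicle replicate 1 to 56867256 in vehicle replicate 3. Of the genes in the count table, 20639 passed the filter on low counts and were tested.

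A large share of the genes tested differed between the groups. SMAD target, integrin and contractile genes were mostly higher with TGF-beta, and interferon-response and detoxification genes mostly lower. The fibronectin gene FN1, the most abundant of the named genes, rose 1.95-fold, from 41050 ± 1894 to 80100 ± 5897 CPM (SD, n = 3 each), and took 4.21% to 4.46% of all counts in the vehicle libraries and 7.05% to 8.06% in the TGF-beta libraries. COL1A1, encoding a chain of type I collagen, rose 1.57-fold, from 2.49% to 3.07% of counts to 3.74% to 4.11%. CCL2, a monocyte-attracting chemokine, fell from 169 ± 14.7 to 14.5 ± 1.21 CPM (SD, n = 3 each).

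By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3866 genes were higher and 4285 lower with TGF-beta, together 39.5% of those tested. At least 2-fold changes were called for 746 higher and 1360 lower genes, and at least 4-fold changes for 218 and 437. In 49.6% of tested genes the CPM values of the groups did not overlap, where chance gives 10% for 3 against 3. The balance of directions depends on the scaling: with library totals in place of TMM, 2210 genes were higher and 7306 lower, so that 23.2% of calls were higher instead of 47.4%, and the median over all genes shifted by -0.16 on the log2 scale.

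**Figure D1:**
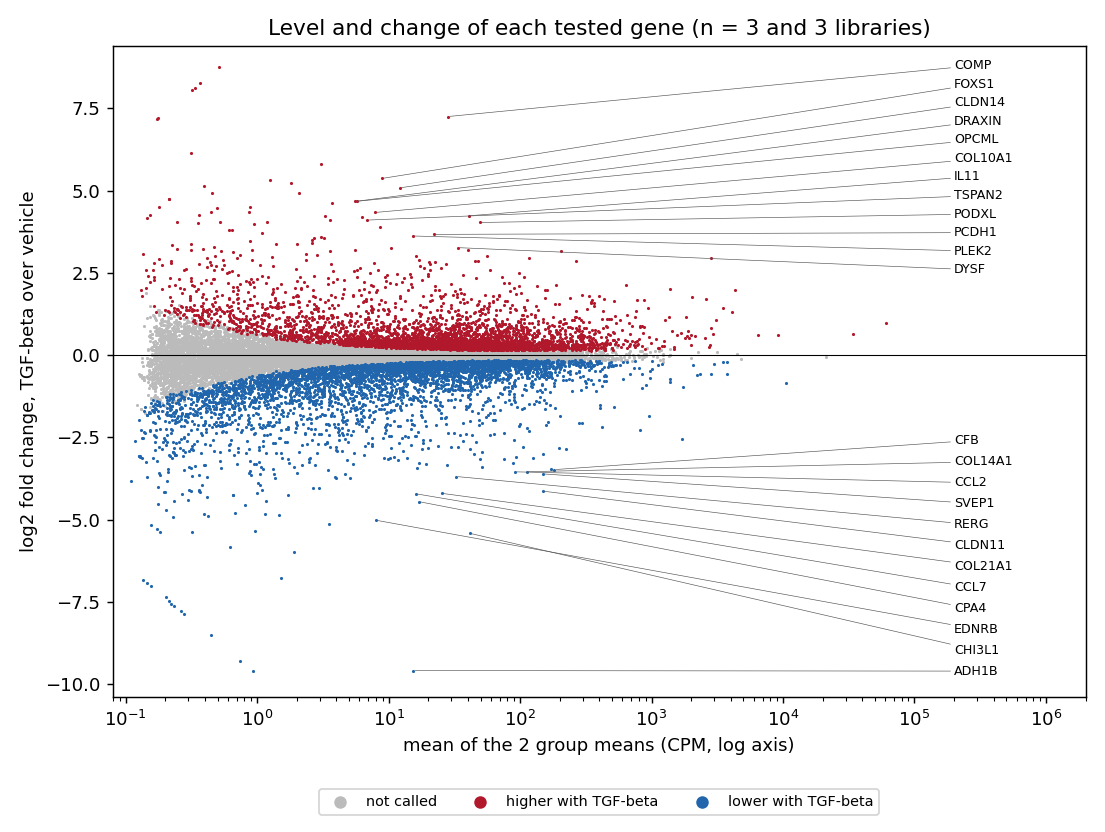
Log2 fold change of each tested gene (TGF-beta over vehicle, vertical axis) against the mean of its group means (CPM, log axis), with red and blue points for the 3866 higher and 4285 lower genes and grey points for genes not called. Lines lead to the names of the 12 largest rises and 12 largest falls under the naming rule, from COMP at 7.26 to ADH1B at -9.58.

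The largest rise among the named genes was in COMP, which encodes cartilage oligomeric matrix protein and lies on chromosome 19 from 18782773 to 18791314 in GRCh38. COMP went from 0.371 ± 0.123 to 56.4 ± 1.72 CPM (SD, n = 3 each), a log2 fold change of 7.26 with a standard error of 0.26. Next came the forkhead transcription factor gene FOXS1 (log2 fold change 5.37), the tight junction gene CLDN14 (5.09), DRAXIN (4.68), OPCML (4.67) and COL10A1 (4.34). Each of these had a mean below 1 CPM over the vehicle libraries. IL11, a cytokine of the interleukin-6 family on chromosome 19 from 55364389 to 55370463, rose 18.9-fold, from 4.11 ± 0.467 to 77.3 ± 5.21 CPM (SD, n = 3 each). The remaining rises were in TSPAN2 (4.11), the sialomucin gene PODXL (4.03), the protocadherin gene PCDH1 (3.67), PLEK2 (3.62) and the membrane repair gene DYSF (3.27). Adjusted p-values from edgeR's quasi-likelihood test for these 12 ran from 6.74e-16 to 9.78e-10.

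Among the falls, ADH1B, an alcohol dehydrogenase gene on chromosome 4 from 99304964 to 99321442, stood apart. It had 4714 counts over the vehicle libraries and 6 over the TGF-beta libraries, 2 in each. The ratio was 815 after scaling for library size, with an exact counting interval of 374 to 2223 at 95%. That interval leaves out the spread between libraries and is too narrow if mates were counted separately. CHI3L1, encoding a secreted glycoprotein related to chitinases, fell from 81.6 ± 5.99 to 1.91 ± 0.491 CPM (SD, n = 3 each), a log2 fold change of -5.42 with a standard error of 0.21. The endothelin receptor gene EDNRB (-5.02), the carboxypeptidase gene CPA4 (-4.45), the chemokine gene CCL7 (-4.21), COL21A1 (-4.20) and the tight junction gene CLDN11 (-4.13) followed. RERG fell by 3.69, SVEP1 by 3.61, CCL2 by 3.54, COL14A1 by 3.54 and the complement gene CFB by 3.48 on the log2 scale. The CFB value cannot be assigned to CFB alone, since an overlapping gene held 92.7% to 94.9% as many counts in each library. For these 12 genes the adjusted p-values of edgeR's quasi-likelihood test ran from 6.74e-16 to 3.43e-14.

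**Figure D2:**
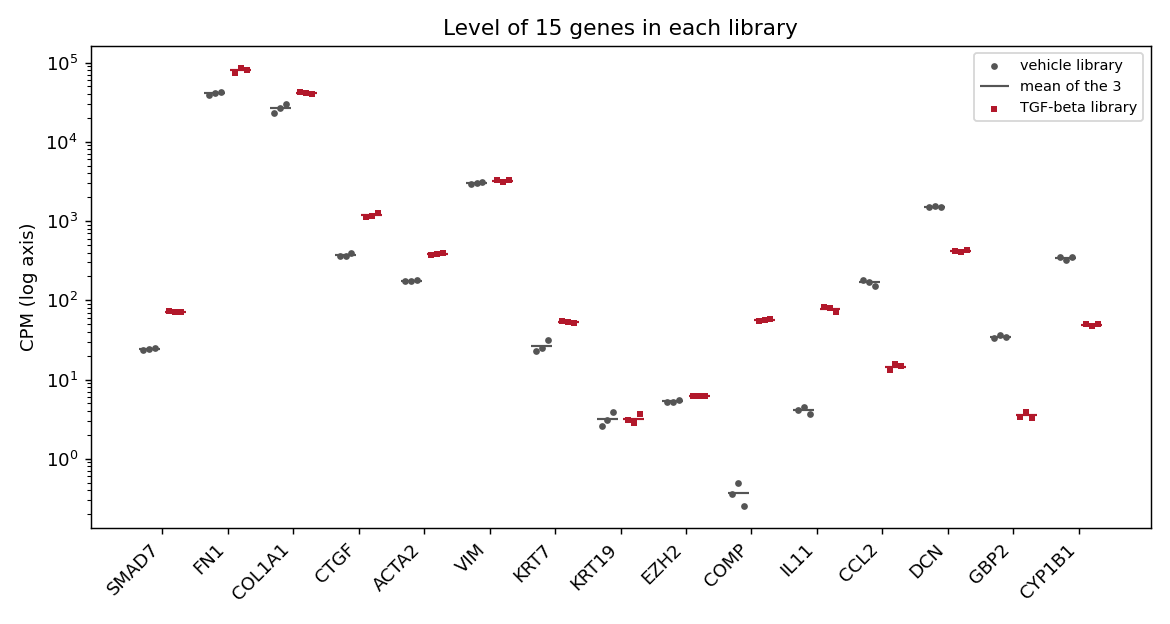
CPM (log axis) of 15 named genes in each of the 3 vehicle libraries (circles) and 3 TGF-beta libraries (squares), with a line at each group mean. SMAD7, FN1 and COMP lie higher in all TGF-beta libraries, CCL2, DCN, GBP2 and CYP1B1 lower, and the groups overlap for VIM and KRT19.

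Known SMAD2/3 targets and feedback genes rose almost together. Of 22 tested, 21 rose and 0 fell over all genes tested, with the same numbers adjusted over the list alone and by DESeq2, limma-voom and an unadjusted p below 0.05, and TSC22D1 at -0.04 was not called. Their median log2 fold change was 1.36. SMAD7, an inhibitor of the pathway, rose from 24.1 ± 0.787 to 71.3 ± 1.05 CPM, and CTGF (CCN2), a matricellular growth factor gene, from 373 ± 17.3 to 1185 ± 60.4 CPM (SD, n = 3 each). PMEPA1 rose by 2.59 and LTBP2 by 1.76 on the log2 scale. Camera gave an adjusted p of 3.69e-15, but the adjusted p was 0.16 with an estimated correlation. Here and for the lists below, that setting also uses far fewer degrees of freedom. A lost call therefore cannot be put down to correlation alone.

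The ligands, receptors and SMADs themselves moved both ways. Of 31 tested, 14 rose and 8 fell (also 14 and 8 adjusted over the list alone), with a median log2 fold change of 0.0793 (-0.082 with library totals, 0.0849 to 0.167 leaving out each library in turn). Its camera adjusted p was 0.116, and 0.0229 with library totals (0.0229 to 0.151 over 11 alternatives). The activin subunit gene INHBA rose 3.23-fold to 541 ± 3.74 CPM, whereas SMAD3 fell from 66.9 ± 0.818 to 16.8 ± 0.322 CPM and the co-receptor gene TGFBR3 from 44.5 ± 0.676 to 10.4 ± 1.14 CPM (SD, n = 3 each). Of the 10 BMP target genes, which read out SMAD1/5 signalling, ID1, ID3, ID4 and SMAD6 rose and BAMBI, ATOH8 and SMAD9 fell, again 4 and 3 adjusted over the list alone. ID1 reached a log2 fold change of 1.92, ID3 1.85 and BAMBI -0.88, and the list had a camera adjusted p of 0.923, a median of -0.06 and a mean of 0.17.

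Collagen genes split by chain. Of 26 tested, 14 rose and 9 fell (14 and 9 adjusted over the list alone). The camera adjusted p was 0.0813, and 0.00531 with library totals (0.00531 to 0.138 over 11 alternatives). Besides COL10A1, COL8A2 rose by 2.45 and COL7A1, encoding the collagen of anchoring fibrils, by 2.15 on the log2 scale, and the basement membrane collagen gene COL4A1 rose from 1732 ± 63.8 to 6834 ± 212 CPM (SD, n = 3 each). COL1A1 went from 26460 ± 3196 to 41540 ± 1671 CPM, while COL3A1 fell from 13540 ± 769 to 7491 ± 257 CPM (SD, n = 3 each). The second chain of type I collagen, COL1A2, stood at 21570 ± 1266 and 20880 ± 446 CPM and was not called (adjusted p = 0.571, edgeR's quasi-likelihood test).

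Other matrix genes also went both ways. Of 45 matrix glycoprotein and proteoglycan genes, 22 rose and 16 fell (24 and 16 adjusted over the list alone). With library totals 19 of these genes rose and 19 fell. Their camera adjusted p was 0.236, and 0.0301 with library totals (0.0301 to 0.41 over 11 alternatives). SDC1, a cell-surface proteoglycan gene, rose 8.04-fold and SPP1, encoding osteopontin, 7.28-fold, while MGP, encoding matrix Gla protein, fell by 2.09 on the log2 scale. Among 23 genes for collagen modification and cross-linking, 16 rose (17 adjusted over the list alone), including LOX at 1.16 and P4HA3 at 1.53, and LOXL4, PCOLCE and CRTAP fell (also 3 adjusted over the list alone). LOXL4, a lysyl oxidase family gene, fell by 2.59 on the log2 scale against the direction of its list. That list had a camera adjusted p of 6.16e-04, and the adjusted p was 0.384 with an estimated correlation. Matrix proteases and their inhibitors had 19 of 31 genes higher and 8 lower (19 and 8 adjusted over the list alone), with ADAMTS4 at 2.76 and the bone-resorbing protease gene CTSK at -2.37. Here the camera adjusted p was 0.00118, and the adjusted p was 0.269 with an estimated correlation.

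Integrin subunits, the receptors that bind matrix, were mostly higher. Of 19 tested, 11 rose and only ITGB8 and ITGB7 fell (11 and 3 adjusted over the list alone), with a median log2 fold change of 0.68. ITGA2 rose from 51.0 ± 4.60 to 218 ± 16.7 CPM and ITGB3 from 13.9 ± 0.171 to 56.2 ± 2.39 CPM, while ITGB8, part of an integrin that activates latent TGF-beta, fell from 21.6 ± 0.911 to 3.75 ± 0.267 CPM (SD, n = 3 each). The fall of ITGB7 was lost without vehicle replicate 1 or 2 or TGF-beta replicate 2 or 3, which left 1 gene lower, as did DESeq2. For integrins camera gave an adjusted p of 6.61e-04, and the adjusted p was 0.16 with an estimated correlation.

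Mesenchymal and contractile genes rose without a rise of every marker. Of 23 mesenchymal transition factors and markers, 15 rose and TWIST1, ZEB2, SOX4 and S100A4 fell (15 and 4 adjusted over the list alone). FOXC2 rose by 2.07, WNT5B by 2.04 and SNAI1, a repressor of epithelial genes, by 1.99 on the log2 scale. Vimentin (VIM) stood at 3032 ± 81.4 and 3230 ± 118 CPM and was not called (SD, n = 3 each; adjusted p = 0.224, edgeR's quasi-likelihood test). The camera adjusted p of this list was 4.07e-04, and the adjusted p was 0.218 with an estimated correlation. Of 32 genes of the actin contractile apparatus, 21 rose and LMOD1, MYH10, LIMA1, MYLK and VCL fell (21 and 5 adjusted over the list alone; 18 and 8 with library totals). Smooth muscle actin (ACTA2) rose 2.19-fold to 385 ± 13.5 CPM, tropomyosin (TPM1) 4.00-fold to 2225 ± 72.6 CPM, ACTG2 3.47-fold and calponin (CNN1) 3.38-fold (SD, n = 3 each). Its camera adjusted p was 1.60e-05, and the adjusted p was 0.353 with an estimated correlation.

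Several genes usual in biliary epithelium were at or near the detection limit in both groups. The E-cadherin gene CDH1 had 6, 21 and 0 counts in the vehicle libraries and 8, 8 and 10 in the TGF-beta libraries and was not tested. EPCAM had 0, 3 and 12 counts against 2, 0 and 5, and GRHL2 and FOXA2 had 0 in all 6 libraries, which allows up to 0.0771 CPM in the shallowest. KRT19 was level at 3.16 ± 0.648 and 3.18 ± 0.432 CPM (adjusted p = 0.998, edgeR's quasi-likelihood test), while KRT7 rose 1.99-fold, from 26.7 ± 4.51 to 53.2 ± 1.48 CPM (SD, n = 3 each). Reads of keratin genes may be shared with their pseudogenes, which the authors' counting could split.

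Of 42 epithelial junction and keratin genes, 29 were tested, 12 rose and 6 fell (13 and 6 adjusted over the list alone). Here the camera adjusted p was 0.135, and 0.012 with library totals (0.012 to 0.357 over 11 alternatives). The desmosome genes DSP and DSG2 rose by 1.84 and 1.21 on the log2 scale. Of 37 cholangiocyte markers and transport genes, 18 were tested, 6 rose and 5 fell, among them GGT1, BICC1, MUC1 and PKD2 (7 and 5 adjusted over the list alone). SOX9, a transcription factor of bile duct cells, rose 5.50-fold from 3.55 ± 0.435 to 19.5 ± 0.484 CPM (SD, n = 3 each). This list had a camera adjusted p of 0.199 and turned to 5 higher and 6 lower with library totals.

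Interferon-response genes fell almost together, while secreted cytokines were divided. Of 37 secreted cytokines and chemokines, 13 rose and 17 fell (13 and 17 adjusted over the list alone; camera adjusted p = 0.236). CXCL6, a neutrophil-attracting chemokine gene, fell from 136 ± 7.42 to 15.3 ± 0.928 CPM (SD, n = 3 each), alongside CCL2 and against IL11. Of 42 interferon-stimulated genes, 40 fell and 0 rose, with the same numbers adjusted over the list alone and by DESeq2, limma-voom and an unadjusted p below 0.05. TAP1 (-0.03) and SAMD9 (0.06) were not called. GBP2, an interferon-induced GTPase gene, fell 9.91-fold from 34.9 ± 1.62 to 3.52 ± 0.376 CPM (SD, n = 3 each), and the antiviral genes MX2 and OAS2 fell by 1.89 and 1.75 on the log2 scale. The median of the list was -1.06 and its camera adjusted p 1.55e-13, and the adjusted p was 0.33 with an estimated correlation.

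Detoxification genes were lower as well. Of 29 tested xenobiotic and oxidant defence genes, 20 fell and TIPARP, SRXN1, GCLM, HMOX1 and NOX4 rose (20 and 5 adjusted over the list alone), with a median log2 fold change of -0.74. CYP1B1, a cytochrome P450 gene, fell 6.99-fold from 344 ± 15.3 to 49.3 ± 1.33 CPM, and the aldo-keto reductase gene AKR1C1 fell 8.89-fold from 88.7 ± 7.97 to 9.98 ± 0.768 CPM (SD, n = 3 each). AKR1C1 has close paralogs between which the authors' counting could split reads. NOX4, which encodes an enzyme that makes reactive oxygen, rose 7.13-fold from 4.94 ± 0.346 to 35.3 ± 0.877 CPM (SD, n = 3 each). Camera gave this list an adjusted p of 1.60e-05, and the adjusted p was 0.16 with an estimated correlation.

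Amino acid and secretory pathway genes rose by smaller amounts. Of 28 serine, glycine and ATF4-linked genes, 22 rose and SHMT1, SLC38A2 and ATF5 fell (22 and 3 adjusted over the list alone; camera adjusted p = 3.39e-07). The adjusted p was 0.219 with an estimated correlation. SLC7A5, an amino acid transporter gene, rose from 176 ± 17.7 to 620 ± 4.25 CPM, VLDLR 2.34-fold and STC2 2.08-fold (SD, n = 3 each). Of 31 genes of endoplasmic reticulum stress and secretion, 25 rose and ATF6 fell (27 and 1 adjusted over the list alone; 16 and 3 with library totals). Their median was 0.35, with HYOU1, encoding a chaperone, at 1.00, SDF2L1 at 0.79 and EDEM1 at 0.75. By camera the adjusted p was 5.36e-08, and the adjusted p was 0.218 with an estimated correlation.

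Cholesterol and glucose genes gave no direction that held under every scaling. Of 25 cholesterol genes, 11 rose and LSS, TM7SF2, HMGCS1 and PMVK fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.448), but with library totals 2 rose and 11 fell. LSS, encoding lanosterol synthase, fell by 0.89, and TM7SF2 fell by 0.51 on the log2 scale. Of 22 glycolysis and glucose uptake genes, 7 rose and PFKL, ALDOC and PDK1 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.158). These became 5 higher and 9 lower with library totals, 10 and 1 without vehicle replicate 3 (camera adjusted p = 0.0443, the lowest of 11 alternatives that reached 0.41), and 7 and 1 without TGF-beta replicate 2. The glucose transporter gene SLC2A1 rose 2.08-fold, HK1 rose by 0.58 and PFKL fell by 0.59 on the log2 scale.

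Proliferation genes showed a mixed and mostly small response. Of 40 S-phase genes, 11 rose and 3 fell, among them TYMS and POLE (10 and 3 adjusted over the list alone; camera adjusted p = 0.0813), which became 8 and 9 with library totals. MCM5, part of the replicative helicase, rose by 0.85, while TYMS, the thymidylate synthase gene, fell by 0.74 on the log2 scale. Without vehicle replicate 3 or TGF-beta replicate 2 the list was called by camera (adjusted p = 0.0443 and 0.0421, with a range up to 0.235 over 11 alternatives). Of 38 mitosis genes, 9 fell, among them TOP2A at -0.59, and BUB3 alone rose at 0.19 (8 and 1 adjusted over the list alone; camera adjusted p = 0.159; 14 lower with library totals). The rise of BUB3 was lost in 6 of the alternatives, including vehicle replicate 2 and TGF-beta replicates 2 and 3 left out in turn, with adjusted p-values of 0.0644, 0.0548 and 0.0833 by edgeR's quasi-likelihood test, within a range of 0.00404 to 0.803 over 11 alternatives. Among 16 CDK inhibitors and senescence regulators, CDKN2B, GADD45B, CDKN1A, CDKN2D and RB1 rose and 6 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.852). CDKN2B, which encodes the cell cycle inhibitor p15, rose from 68.9 ± 7.37 to 193 ± 3.88 CPM, GADD45B rose 3.07-fold, and CDKN1C fell from 15.6 ± 2.94 to 4.77 ± 0.201 CPM (SD, n = 3 each).

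EZH2, the methyltransferase of Polycomb repressive complex 2, had 5.36 ± 0.200 and 6.24 ± 0.0436 CPM and was not called (SD, n = 3 each; adjusted p = 0.111, edgeR's quasi-likelihood test). Of 16 tested genes of the Polycomb list, JARID2 (0.43) and KDM6B (0.28) rose and PHF19 (-0.28), AEBP2, RBBP4 and RBBP7 fell (2 and 4 adjusted over the list alone; 1 and 7 with library totals; camera adjusted p = 0.923), with a median of -0.01 and a mean of 0.00. There were 2 lower genes without vehicle replicate 1 or 2 or TGF-beta replicate 1 or 2. The call of KDM6B was lost without TGF-beta replicate 2 (adjusted p = 0.0889) and that of PHF19 without vehicle replicate 2 or TGF-beta replicate 2 or 3 (adjusted p = 0.144, 0.119 and 0.0752, edgeR's quasi-likelihood test). Over 11 alternatives the adjusted p of KDM6B ranged from 0.00352 to 0.231 and that of PHF19 from 0.00106 to 0.144.

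Genes of other signalling pathways were divided. Of 23 YAP/TAZ target genes, 11 rose and 7 fell (11 and 7 adjusted over the list alone; 9 and 9 with library totals; camera adjusted p = 0.199), with CTGF at 1.67, IGFBP3 at 1.62 and ANKRD1 at 1.36. Of 26 Notch and Hedgehog pathway genes, 9 rose and 8 fell (9 and 8 adjusted over the list alone; camera adjusted p = 0.69), with a median of -0.04 and a mean of 0.00. The Hedgehog co-receptor gene GAS1 fell from 166 ± 12.4 to 19.7 ± 2.33 CPM, while HHIP rose from 5.60 ± 0.732 to 39.5 ± 2.76 CPM and GLI1, both targets of the pathway, from 4.30 ± 0.610 to 10.7 ± 0.237 CPM (SD, n = 3 each). Of 20 immediate early and heat shock genes, 10 rose and EGR1, EGR3, HSPA1A, HSPA1B and HSP90AA1 fell (10 and 5 adjusted over the list alone; camera adjusted p = 0.116, and 0.0467 with library totals, in a range of 0.0467 to 0.195). With library totals 8 genes of this list rose and 7 fell. EGR2 rose 8.15-fold and IER2 1.81-fold, whereas EGR1 fell by 1.29 on the log2 scale.

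Markers of other cell types were followed as well. Fibroblast and stellate cell markers were abundant in the vehicle libraries, with PDGFRB at 889 ± 47.5 and DCN, encoding decorin, at 1507 ± 29.9 CPM (SD, n = 3). Of 24 tested, 6 rose and 13 fell (6 and 13 adjusted over the list alone), with HGF at -2.35, DCN at -1.85 and PDGFRA at -1.61. Their camera adjusted p was 0.0306, but 0.121 with library totals (0.0164 to 0.121 over 11 alternatives), and the adjusted p was 0.218 with an estimated correlation. Of 14 tested endothelial markers, 9 rose and EMCN fell (11 and 1 adjusted over the list alone; camera adjusted p = 6.72e-04). The adjusted p was 0.218 with an estimated correlation. Of these markers, 6 were higher with library totals, 7 by DESeq2 and 6 to 10 leaving out each library in turn. Their levels were low, with ROBO4 rising from 3.35 ± 0.168 to 13.1 ± 0.951 CPM, the angiopoietin receptor gene TEK from 14.8 ± 0.530 to 34.6 ± 0.489 CPM and STAB1 from 5.56 ± 0.808 to 10.9 ± 0.665 CPM (SD, n = 3 each).

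Of 7 tested leukocyte markers, CSF1R, FCER1G and LAPTM5 rose and CD68 and CD163 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.852), and of these only CD68, at 35.6 ± 2.02 and 21.2 ± 0.683 CPM, was above 3 CPM (SD, n = 3 each). Of 25 hepatocyte markers, 6 were tested and 0 called by edgeR in either direction, adjusted over the list alone included, with 1 lower at an unadjusted p below 0.05 and 0 called by DESeq2 or limma-voom. With library totals 1 hepatocyte marker was called lower, and 1 without vehicle replicate 1. For the 6 tested the camera adjusted p was 0.923, in the upward direction against a median of -0.11. The 13 mitochondrially encoded genes took 0.675% to 1.02% of counts in the vehicle libraries and 0.689% to 0.888% in the TGF-beta libraries. By edgeR 0 of them were called, adjusted over the list alone included, with 4 higher at an unadjusted p below 0.05 and 0 called by DESeq2 or limma-voom (camera adjusted p = 0.266). Without vehicle replicate 2, which had the highest share, 9 were higher and the camera adjusted p was 0.0191 (0.0191 to 0.868 over 11 alternatives). Without TGF-beta replicate 3, 5 of the 13 were higher.

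**Figure D3:**
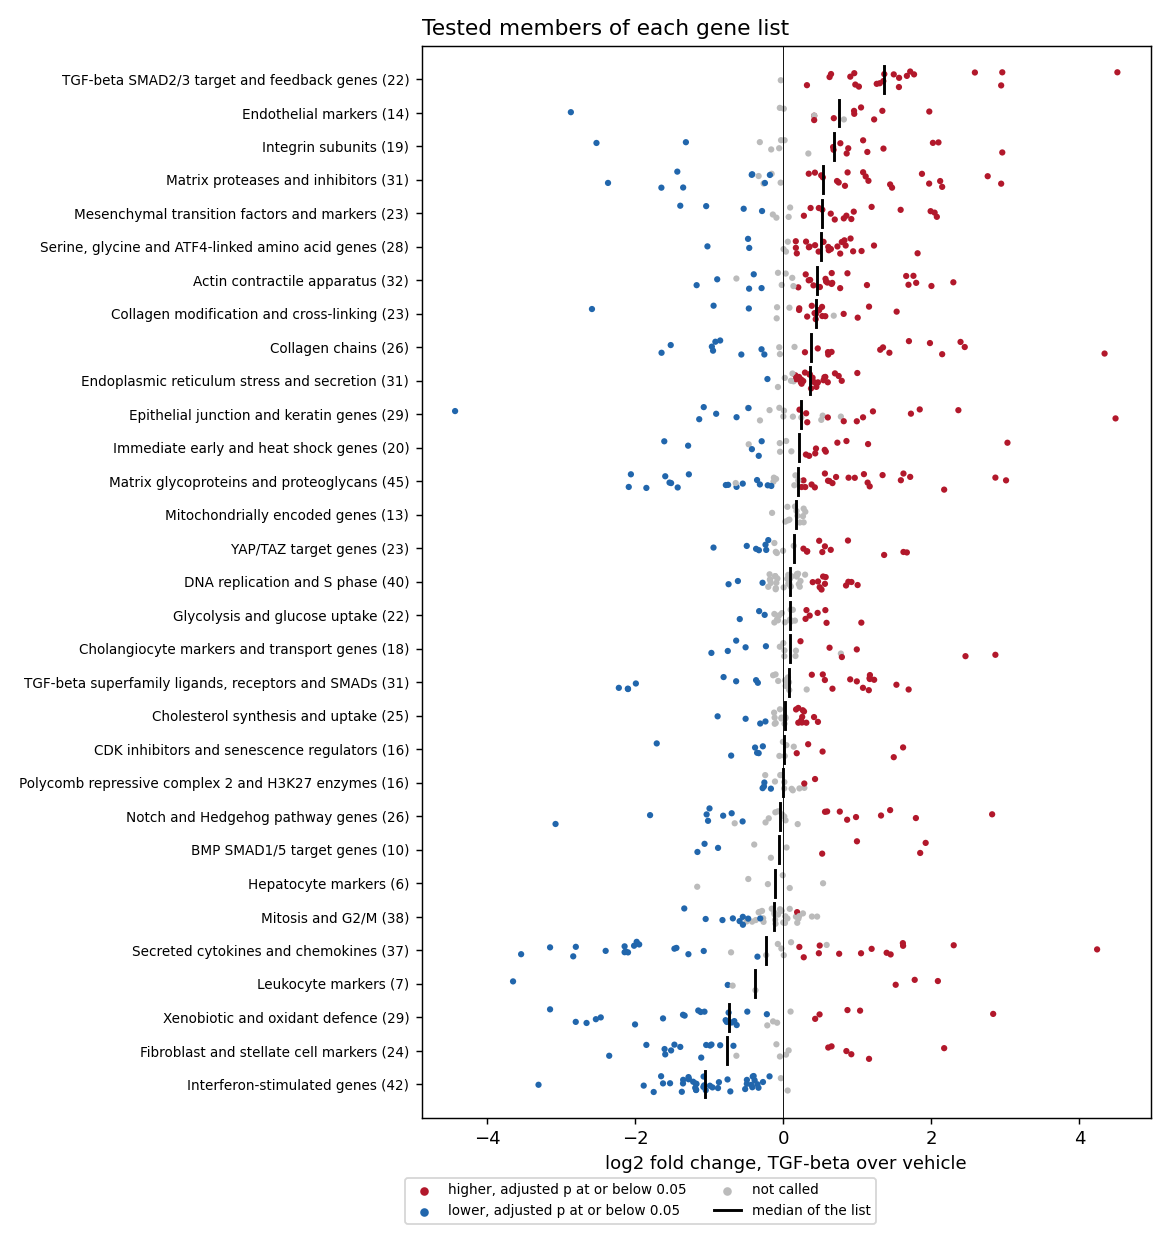
Log2 fold change (horizontal axis, TGF-beta over vehicle) of the tested members of the 31 gene lists, with red and blue points for higher and lower genes, grey points for genes not called and a black bar at each list's median. The SMAD2/3 target list lies highest with a median of 1.36 and the interferon-stimulated list lowest with -1.06.

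Of the 31 lists, camera called 12, of which 9 shifted up and 3 down. With an estimated correlation, 0 lists passed the adjusted threshold and 7 an unadjusted p of 0.05, while fry called 22. The estimated correlation comes with far fewer degrees of freedom, so the lost calls do not show that correlation removed them. The labels give no origin for the replicates, so these p-values measure the spread between the libraries only.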

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

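The likelihood-ratio test, the reference chromosomes, the single gene per overlapping pair and some alternatives for single lists were chosen after the results were seen. Genes higher and lower, 3866 and 4285 as reported, became 2210 and 7306 with library totals, 1889 and 2523 when tested against a fold of 1.2, and 746 and 1360 with a minimum of 2-fold. The last pair of settings asks for larger changes by construction. With library totals the median over all genes shifted by -0.16 on the log2 scale. The 2210 higher genes were all among the 3866, and the 7306 lower genes included all 4285. The other scalings, filters and tools gave 3490 to 4115 higher and 3671 to 4694 lower genes, and leaving out each library in turn 3288 to 4271 and 3568 to 4110. No gene was called in opposite directions under any alternative run. The likelihood-ratio test without filter called 3711 and 3955 genes, the numbers in the authors' deposited table.

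Of 31 lists, 12 were called, 0 with an estimated correlation (7 unadjusted) and 22 by fry, which asks another question. A correlation above the preset 0.01 is argued against as the cause for the integrin, xenobiotic, and fibroblast and stellate lists. Their estimated correlations were -0.00447, 0.00852 and -0.0173, and their calls were lost as well. With an estimated correlation, camera also takes its degrees of freedom from the few libraries and not from the number of genes. That difference remains for the lists just named. How much each part counted for the other lists was not tested. Leaving out each library in turn gave 12 to 14 lists. Over the 110 named genes, 1198 of 1210 alternatives kept the call or its absence, and the 12 lost calls were those of BUB3, KDM6B and PHF19. Among the 1198 were 7 changes of sign in the uncalled genes KRT19 and VIM. Most of the 110 named genes were picked for large called changes in the same fit, so their stability does not stand for all genes. Over the lists, 369 of 401 alternatives kept the call or its absence, 13 lost a call, 19 gained one and 0 reversed one. Leaving out each library in turn, the medians near 0 of the BMP target, Polycomb, Notch and Hedgehog, and hepatocyte lists lay between -0.226 and 0.0387.

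The vehicle and TGF-beta libraries share replicate numbers. Deviations from the group means correlated at -0.38, 0.075 and -0.086 between same-numbered libraries, and at -0.33 to 0.33 between the others. No pairing by number was seen, but so few libraries cannot exclude a weak shared effect. With the replicate block 3582 genes were higher, 4058 lower and 12 lists called, and 7 mitochondrially encoded genes were higher. No vehicle library correlated best with the TGF-beta library of its own number. Among the TGF-beta libraries only replicate 2 correlated best with its own number, at 0.075. Depth limits the low genes: 3 counts stand for 0.0528 to 0.0771 CPM. The simulated recovery of 70% for 1.5-fold changes was not split by level or depth, so it does not measure this limit.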

Other observations

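The tests of families of gene symbols and of single explanations were chosen after the results were seen; the splits of the libraries were planned. Among 185 families of protein-coding genes sharing a symbol stem, tested in both directions (370 Fisher's exact tests, 2-sided, Benjamini-Hochberg adjusted), 14 families had an adjusted p of 0.05 or below, in 15 tests. All 10 tested CXCL chemokine genes were lower (adjusted p = 7.59e-05), with a median log2 fold change of -2.14, and the 10 were lower under each scaling run. CXCL1 went from 183 ± 10.4 to 26.2 ± 1.86 CPM and CXCL8 from 232 ± 39.3 to 85.3 ± 9.21 CPM (SD, n = 3 each). Keratin genes were more often higher, 10 of 16 against 22.2% of the background (adjusted p = 0.0202), also 10 under each scaling. KRT34 rose from 4.19 to 18.7 CPM, and KRT14, KRT16 and KRT79 rose from below 0.1 CPM to between 0.856 and 0.938 CPM. Genes of a family are not independent, and reads shared between close copies count in each.

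Replication-dependent and related histone genes were more often lower, 13 of 22 against 24.0% of the background (adjusted p = 0.0183), led in level by HIST1H2AC, from 32.8 to 14.9 CPM. Aldehyde dehydrogenase genes were lower in 11 of 16 (adjusted p = 0.00868) and semaphorin genes in 11 of 19 (adjusted p = 0.041), although SEMA7A rose from 41.7 to 371 CPM. Of 16 TNF receptor superfamily genes 10 were lower (adjusted p = 0.0353), while TNFRSF12A, the receptor for TWEAK, rose from 56.7 to 157 CPM. Of 10 exosome complex genes 7 were higher (adjusted p = 0.041), but 2 with library totals. All 12 PCDHGA protocadherin genes, which overlap and share their last exons, were lower (adjusted p = 6.5e-06), as they were under each scaling. Of 43 genes with the stem IL 22 were lower (adjusted p = 0.0057), and of 46 with the stem CD 21 (adjusted p = 0.0404). In the histone, aldehyde dehydrogenase, semaphorin and TNF receptor families the lower genes outnumbered the higher ones under each scaling run.

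The smallest adjusted p of these Fisher's exact tests was that of zinc finger (ZNF) genes, called less often than the background in either direction. Of 482, 37 were higher (adjusted p = 2.49e-15) and 79 lower (adjusted p = 0.00332), but 8 higher and 208 lower with library totals. The background was all protein-coding genes tested, without matching for expression level. Whether ZNF genes were called less often than other genes of the same level was not tested. Mitochondrial ribosomal (MRPL) genes were less often lower, 1 of 49 (MRPL42; adjusted p = 0.00316), against 15 with library totals. Ribosomal RPL genes were less often higher, 1 of 50 (RPL7L1; adjusted p = 0.0057), and 17 were lower, or 45 with library totals and 5 to 23 leaving out each library in turn. Genes with the stem PPP were more often higher, 27 of 66 (adjusted p = 0.0202), or 11 with library totals.

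Albumin (ALB) had 166 counts in vehicle replicate 2 and 7, 4, 6, 0 and 0 in the other libraries, and APOB had 64 there and 0, 4, 0, 0 and 2 elsewhere.

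Several epithelial genes lay near the floor in both groups. Too little depth is argued against, since 3 counts stand for at most 0.0771 CPM in any library. Loss under TGF-beta is argued against as the cause for CDH1, EPCAM, GRHL2, FOXA2, CLDN3 and ESRP1, none of which was above 0.404 CPM in any vehicle library. Cells other than biliary epithelium in the cultures may be a source, with PDGFRB at 889 CPM in the vehicle libraries, but a stromal state of the labelled cells would give the same transcripts, and the 2 cannot be told apart without a measure per cell.

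Of the interferon-stimulated genes, 40 of 42 fell. A single unusual library is argued against as the source, since the median log2 fold change stayed at -0.947 or below whichever library was left out. Library scaling is argued against too, with medians of -1.05 or below under the other scalings run. A response of these cells to TGF-beta could explain it, as a hypothesis, and a difference between the groups other than the treatment was not tested and stays open.

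Fibroblast and stellate markers moved both ways, 13 lower and 6 higher. A lower share of fibroblast-like cells after TGF-beta would by itself lower them all, and as the whole cause is argued against by the 6 that rose, COL1A1, COL6A3, FAP, LOX, MFAP5 and TWIST2. Another 5 of the 24 tested were not called. PDGFRB stood level at 889 ± 47.5 CPM with vehicle and 911 ± 36.4 CPM with TGF-beta (SD, n = 3 each). THY1 stood at 43.4 ± 2.8 and 45.6 ± 3.22 CPM in the same order. A lower share together with a change of expression within such cells was not tested and stays open.

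The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3866 higher and 4285 lower genes, and the highest of the other splits 0 genes by edgeR's quasi-likelihood test, with up to 408 at an unadjusted p below 0.05, so that 1 of 10 splits gave as many genes higher and 1 as many lower. The real split gave 12 lists, as did 2 of the other splits, so that 3 of 10 gave as many. Every other split mixes vehicle and TGF-beta libraries in both groups. Part of the treatment difference stays between such groups, and the rest adds to the spread within them. The splits therefore cannot say how many genes or lists chance would give.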
